A study of Rattus norvegicus with 2 samples.

How the data were processed

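ChIP with an antibody against H3K27me3 was carried out on freshly dissected rat sciatic nerve, and 2 libraries were sequenced. Per the labels' protocols, tissue was fixed in 1% formaldehyde for 10 min, chromatin was sonicated to fragments averaging 0.5 to 2 kb, and each ChIP used 300 µg of chromatin and 5 µg of antibody. The header gives a fragment length of 168 bp for the combined ChIP tags. The labels also give P28 under a passage field, whose meaning for tissue is not stated, and it was not used. The submitters' processing notes name CASAVA 1.8.2, Bowtie and HOMER. Per the file headers, regions were called with HOMER findPeaks in region mode, with a peak size of 150 bp and a minimum distance of 370 bp, on 1 combined ChIP tag directory against 1 combined input directory. The header does not state which libraries were combined, so that the list holds exactly these 2 is not known. The caller required 14 tags per window (false discovery rate 0.001), a fold of 4 and a Poisson p of 1e-04 over input, and the same fold and p over a local region of 10000 bp. It removed 1161 putative peaks for input, 127 for clonal tags and 0 for local signal, per the file headers. The local requirement thus did not shape the list. Putative peaks numbered 489809 before they were stitched into the 90174 listed regions. The versions of Bowtie and HOMER are not given in the sources used here.

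The deposited file gives for each region a ChIP signal, the tag number scaled by the authors' peak caller to 10000000 tags in all, and a second signal scaled to the input. It also holds the input signal, the tags of the combined input, where 0.5 stands for 0, as in 7215 regions. The deposited fold is the ratio of the scaled ChIP tags to input tags, so in those 7215 regions it rests on 0.5 tags. The deposited clonality value was not used. The deposited p-value is the caller's Poisson p-value over input, at most 7.14e-05, and is a filter within this list, not a test between animals. The deposited score of the caller and the p-value were not used in any comparison. Column names and units are those of the file header.

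ChIP tags per region were recovered as the normalized signal times the header's total of 46826704 tags over 10000000. The result was whole within 0.24 tags for 100% of regions, and the tags summed to 5856622 against 5856593 in the header. The input total of 41.2 M tags was derived from the constant ratio of the 2 scaled columns. Pooled ratios are summed ChIP tags over summed input tags, each divided by its total, with input 0 where the file writes 0.5. Intervals on ratios of 2 tag numbers are 95% exact binomial (Clopper-Pearson) intervals, and those on numbers of regions are exact Poisson intervals. All cover counting error only. Tags are not corrected by molecular identifiers, and neighbouring regions are not independent.

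The genome build is not given in the sources used here. Regions ran past the last gene of the GRCr8 reference gene table on 13 of 21 chromosomes, so that table's coordinates were not combined with the file's. Positions are printed as the file gives them, and whether its starts count from 0 or 1 is not given. The tests planned on gene lists, on gene symbol families, on Hox genes, on injury genes against myelin genes and on promoter CpG content need gene positions in the file's build. They were not run, and no gene is named. The rule for named genes, fixed before the data were examined, could be applied only in its part on the 20 widest domains, which are named here by position. The widest continuous regions, the highest folds among regions with 20 or more input tags, the 1 Mb bins, the 4 mapped domains and the pairs of regions inside domains were chosen after their values were seen.

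Regions on the 20 autosomes and X (90129) entered the comparisons, and 45 on 36 unplaced or random scaffolds did not. Domains were made by merging regions 3 kb or less apart. Tags and ratios of a domain are those of its called regions, without the sequence between them. Width classes were set at 150 bp, 500 bp, 2 kb, 5 kb and 10 kb. Comparisons of width classes and of distance to wide regions took the 20 autosomes as units and a two-sided sign-flip permutation test with 100000 resamples. X was compared with the autosomes by its rank among 21 chromosomes. The file is 1 combined list with no column per library, so no test between samples, no leaving out of a replicate and no count of other splits of the samples could be made. Alternatives fixed before the data were examined were the regions at or above the median fold, regions per Mb in place of covered share, and merging distances of 1 and 10 kb. The comparisons of width classes, the test of distance to wide regions and the remaining alternatives were added after seeing the data. The scripts were tested on simulated data. Narrow regions placed evenly over 20 autosomes gave a mean ratio of 1.03 (0.807 to 1.33), 200 of 200 planted domains were recovered by merging, and the sign-flip test gave p under 0.05 in 3.6% of 500 draws without effect. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.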

Results

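H3K27me3, the trimethyl mark on lysine 27 of histone H3 that Polycomb repressive complexes place on silent chromatin, was mapped by ChIP-seq in the sciatic nerve of male Sprague Dawley rats. The sciatic nerve holds myelinating and non-myelinating Schwann cells together with fibroblasts, perineurial, endothelial and immune cells, so the map is of the whole nerve. The 2 libraries form 1 group. The directory names in the header of the peak list carry the word Sham, which the sample labels do not use. The list was called on 1 combined set of ChIP tags, which the header does not state to be exactly these 2 libraries: 46.8 M ChIP tags against 41.2 M input tags, the second total worked out from the scaled columns. The depth of each library is not known, no value exists per library, and no spread between replicates can be given. Intervals below cover counting error only, and a spread over autosomes is not a spread over animals. The genome build of the positions below is not given in the sources used here, and genes at these positions were not analysed here.

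The mark was spread over 90174 regions that together covered 36.3 Mb. These regions held 12.5% of the ChIP tags and 1.27% of the input tags, a pooled ChIP to input ratio of 9.83 after scaling to the 2 totals. The fold over input given by the authors' peak caller had a median of 8.21, with quartiles of 5.86 and 14.07. Most regions were small. The median width was 150 bp, the peak size set for the caller, and 56.4% of regions had exactly this width. Per the labels' protocols chromatin fragments averaged 0.5 to 2 kb, which limits the resolution. A width of 150 bp is thus not the size of a marked stretch. The narrowest region spanned 122 bp. The widest region spanned 34349 bp. Regions of 2 kb or wider numbered 2625, or 2.91% of all (95% exact binomial interval 2.80% to 3.02%), and 4.50% among regions at or above the median fold. The interval takes regions as independent draws, which neighbouring regions are not. The 2625 regions held 46.6% of the ChIP tags found in all regions. The 216 regions over 10 kb held 16.7% of these tags.

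The amount of mark per kb was higher in regions over 2 kb than in narrower ones, and highest over 10 kb. Regions of 150 bp or less held 129.9 ± 1.1 ChIP tags per kb (SD over 20 autosomes), and regions between 150 and 500 bp held 130.0 ± 3.5. Regions of 0.5 to 2 kb held 134.9 ± 13.2, and their ChIP to input ratio, 7.97 ± 0.64, was below the 8.28 ± 0.25 and 8.28 ± 0.30 of the narrower classes. Paired by autosome it was lower than in regions of 150 bp or less on 17 of 20 autosomes, by 0.306 ± 0.548 (two-sided sign-flip permutation test, p = 0.0196). It was lower than in regions between 150 and 500 bp on 18 of 20, by 0.310 ± 0.386 (same permutation test, p = 0.00277). In the 0.5 to 2 kb class chromosome 19 held 183.1 tags per kb at a ratio of 9.91, the highest of the 20 autosomes in both. A region of this class there, from 67047832 to 67049005, held 619 input tags, or 527.7 per kb, at a fold of 19.06. This single region raises both values of chromosome 19, and the class values without it are not given here. The median fold was 7.59 in regions of 0.5 to 2 kb, 7.92 in regions of 150 bp or less and 8.27 between 150 and 500 bp. The density was 175.2 ± 15.3 tags per kb in regions of 2 to 5 kb and 230.3 ± 24.3 in regions of 5 to 10 kb. Regions over 10 kb reached 296.7 ± 23.0 tags per kb. Input was 13.8 ± 0.47 tags per kb in the narrowest class and 15.3 ± 1.6 in the widest. Regions over 10 kb thus held 2.28 ± 0.18 times the ChIP density of regions of 150 bp or less, and the ratio lay above 1 on 20 of 20 autosomes (two-sided sign-flip permutation test of log2 ratios, p = 1e-05, the smallest that 100000 resamples can give). The input density of the same classes differed 1.11 ± 0.10 times, above 1 on 18 of 20 autosomes (p = 9e-05, same permutation test). The ChIP to input ratio differed 2.07 ± 0.20 times. The caller builds wide regions by stitching windows that each pass a tag minimum of 14, so width and density are not independent measurements. The same holds for width and ratio. The lower ratio at 0.5 to 2 kb is therefore not by itself a measure of less mark, and its p-values describe the list as called.

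**Figure D1:**
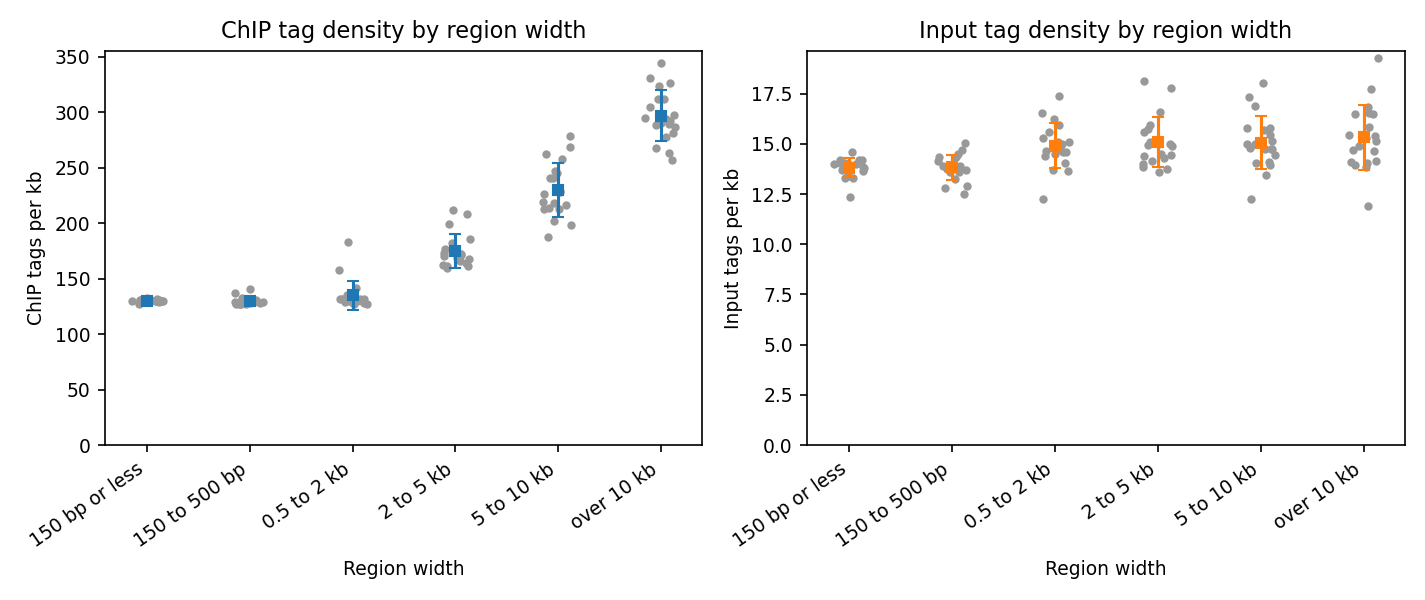
ChIP tags per kb (left) and input tags per kb (right) inside H3K27me3 regions, by region width. Grey points are the 20 autosomes, squares and bars the mean and SD over them; mean ChIP density is 129.9 tags per kb in the narrowest class and 296.7 in the widest, while mean input stays between 13.8 and 15.3.

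The widest continuous regions lay on chromosomes 6, 20, 2 and 3. The first covered chromosome 6 from 86920821 to 86955170, with a fold over input of 16.02 (95% counting interval 14.7 to 17.5). The second covered 32.4 kb of chromosome 20 from 57184025 to 57216459, at 18.01 (16.5 to 19.7). A region of 31.9 kb on chromosome 2, from 140799758 to 140831656, had a fold of 10.58 (9.65 to 11.6), below those of the other members of the 5 widest. On chromosome 6 a further region of 30.7 kb, from 155679047 to 155709782, had a fold of 16.44 (15.1 to 17.9). On chromosome 3 a region of 30.7 kb, from 102313599 to 102344328, had a fold of 22.47 (20.4 to 24.7). The intervals of the chromosome 2 region and of the chromosome 3 region do not overlap with those of any other member of the 5.

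To describe stretches with many neighbouring regions, regions 3 kb or less apart were merged. Whether such regions are parts of 1 continuous domain was not tested. Merging gave 42127 domains on the numbered chromosomes and X. Of these, 533 spanned 20 kb or more, 69 spanned 50 kb or more and 12 spanned 100 kb or more. The 533 domains held 11.2% of the regions and 38.8% of the ChIP tags in regions, and their median covered share was 56.2%. Their number depended on the merging distance, with 179 domains of this size at 1 kb and 2220 at 10 kb, and on the regions kept, with 194 at 3 kb among regions at or above the median fold. Which domains were widest depended on it too, since 7 of the 20 widest overlapped a member of the 20 widest at 1 kb and 9 at 10 kb. A single region made up 65.1% of all domains.

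The widest merged domain lay on chromosome 5 from 145006548 to 145158102, spanned 151.6 kb and was built from 72 regions. Its ChIP to input ratio was 7.19 (95% counting interval 6.84 to 7.56). Ratios of domains use only the tags inside their called regions, each of which had to pass a fold of 4. The sequence between those regions is left out, and regions covered 36.1% to 89.8% of the 20 widest domains. The ratios are thus not the enrichment of the whole span. A domain of 146.4 kb on chromosome 2, from 217959183 to 218105549, had a ratio of 13.4 (12.8 to 14.0). The domain on chromosome 3 from 68044764 to 68190203 spanned 145.4 kb at a ratio of 15.1 (14.3 to 15.9). Chromosome 1 carried a domain of 141.4 kb from 271846294 to 271987723, at 14.1 (13.3 to 14.9), and one of 133.4 kb from 142168313 to 142301673, at 13.04 (12.4 to 13.8). On chromosome 10 a domain of 134.9 kb from 83904905 to 84039787 was covered to 89.8% by regions, the highest share among the 20 widest, at a ratio of 14.0 (13.4 to 14.8). It was followed on the same chromosome by a domain of 121.8 kb from 84169855 to 84291677 with a lower ratio of 8.18 (7.72 to 8.67). A domain of 100.3 kb on chromosome 7, from 142282812 to 142383138, consisted of only 20 regions, was covered to 89.6% and had a ratio of 15.1 (14.4 to 16.0). Of the other members of the 20 widest, those on chromosomes 12, 15, 8 and 11 had the higher ratios. They ran from 19088581 to 19199467 and from 43886535 to 43978759 on chromosome 12, at 15.95 and 15.96. The others ran from 50152383 to 50246577 on chromosome 15, at 13.8, from 98204276 to 98283323 on chromosome 8, at 16.2, and from 34979095 to 35056261 on chromosome 11, at 13.8. Lower ratios were found from 180760851 to 180885480 on chromosome 4, at 9.11, from 55065690 to 55180996 on chromosome 1, at 7.11, and from 64453029 to 64547420 on chromosome 18, at 7.83. Chromosome 3 held a further 4 such domains, from 162320915 to 162427020 at 6.92, from 162951188 to 163050915 at 7.20, from 89778123 to 89862063 at 8.71 and from 50532894 to 50616231 at 8.58. Among the 20 widest domains, 9 had ratios from 6.92 to 9.11 and were built from 47 to 88 regions each, and 11 had ratios from 13.04 to 16.2 with 11 to 70 regions each. No gap of this kind was present over all 533 domains, of which 170 had ratios between these ranges.

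**Figure D2:**
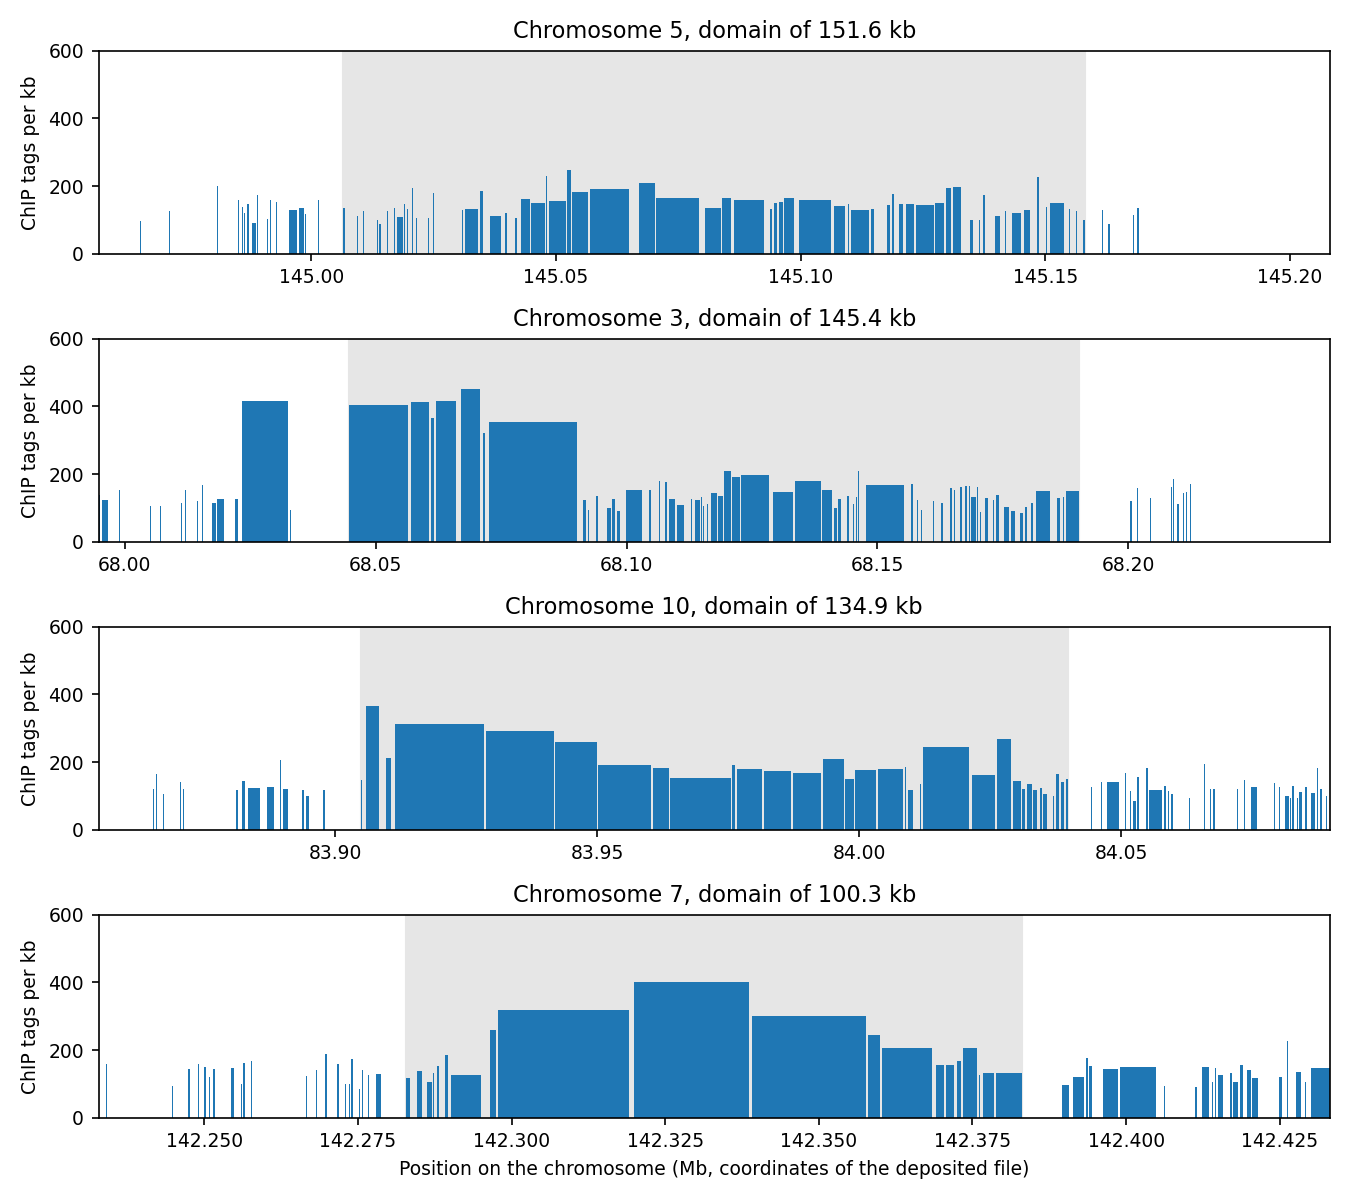
Maps of 4 of the 20 widest merged domains, with position in Mb on the x axis and ChIP tags per kb of each region as bar height; each bar is as wide as its region and the grey band marks the merged domain. The regions of 5 kb or wider stay between 159.5 and 192.3 tags per kb in the chromosome 5 domain and between 168.8 and 403.7 in the chromosome 3 domain, and regions cover 89.8% and 89.6% of the chromosome 10 and 7 domains.

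ChIP density differed more between the wider regions of some of these domains than of others. Of the 20 widest, 14 held at least 2 regions of 5 kb or wider. The ChIP density of the highest of these over that of the lowest was 1.85 to 2.39 in 7 domains and 1.06 to 1.43 in the other 7. The first 7 held 3 to 8 such regions and the other 7 held 2 to 4. A ratio of highest to lowest tends to grow with the number compared. Its 95% counting interval included 1 in 1 of the 14 domains. Narrower regions were not compared. In the chromosome 3 domain the region from 68044764 to 68056350 held 403.7 tags per kb and the region from 68147819 to 68155375 held 168.8, a ratio of 2.39 (95% counting interval 2.25 to 2.55). In the first chromosome 10 domain the density was 311.7 tags per kb from 83911418 to 83928516 and 153.6 from 83963954 to 83975491, a ratio of 2.03 (1.92 to 2.14). The chromosome 7 domain held 400.9 tags per kb from 142319920 to 142338609 and 206.6 from 142360245 to 142368402, a ratio of 1.94 (1.84 to 2.05). In the chromosome 5 domain the regions of 5 kb or wider differed by a ratio of at most 1.21 (1.11 to 1.31). These pairs are the highest and the lowest region of 5 kb or wider in each domain, picked for their difference.

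The highest folds among regions with at least 20 input tags belonged to shorter regions. A region of 2.96 kb on chromosome 1, from 244366651 to 244369611, had a fold of 40.46, but only 22 input tags lay under it and the interval ran from 26.6 to 64.9. A region of 3.55 kb on chromosome 19, from 34375344 to 34378897, had a fold of 39.15 (27.1 to 58.7). The region of 11.6 kb at the start of the chromosome 3 domain, from 68044764 to 68056350, had a fold of 30.03 (25.3 to 35.9) and was the only member of the 10 highest over 10 kb wide. The intervals of these regions overlap, so their order is not resolved at this depth. A ranking by fold also favours regions with few input tags. As classes, wider regions had the higher folds, with medians of 9.87 at 2 to 5 kb, 12.9 at 5 to 10 kb and 17.1 over 10 kb.

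Covered length differed between 1 Mb bins. The 10% of autosomal 1 Mb bins with the most covered length, 276 of 2755 bins, held 48.1% of the covered length. The bins were ranked by the same covered length, and no share under an even spread is given here. No region lay in 172 bins (6.24%). On 7 autosomes there were stretches of 5 Mb or longer without a region, and whether tags map there is not known. The most covered bin ran from 84000001 to 85000000 on chromosome 10, with 268 regions over 237.5 kb, and the next was its neighbour from 83000001 to 84000000, with 182 regions over 226.6 kb. Chromosome 1 followed with 198.9 kb in the bin from 272000001 to 273000000 and chromosome 3 with 181.1 kb from 162000001 to 163000000. Narrow regions lay within 50 kb of wide ones more often than an even spread would give, although most lay farther away. On autosomes 8.41% ± 2.35 of the regions of 150 bp or less lay within 50 kb of a region of 5 kb or wider, while 2.04% ± 0.75 of the span lay this close (SD over 20 autosomes). The ratio was 4.30 ± 0.87 and exceeded 1 on 20 of 20 autosomes (two-sided sign-flip permutation test, p = 1e-05, the smallest that 100000 resamples can give). Part of this comes from uneven density between 1 Mb bins, and against narrow regions placed evenly within their own bins the ratio was 1.89 ± 0.21.

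Chromosomes differed in how much of their span lay in called regions, and X had the least. The rats were male, so each cell has a single X. X had 606 regions over a span of 154.1 Mb, or 3.93 per Mb (95% counting interval 3.62 to 4.26), against 33.8 ± 8.7 on the 20 autosomes. Regions covered 0.208% of X and 1.35% ± 0.41 of the autosomes, 6.5 times as much. X ranked lowest of 21 chromosomes in both measures (one-sided exact rank p = 0.0476, the smallest that 21 chromosomes can give, and 0.0952 two-sided). Chromosome 10 had the highest density, 54.9 regions per Mb (53.5 to 56.3), followed by chromosome 8 with 49.3 (48.1 to 50.5) and chromosome 12 with 44.1 (42.4 to 45.9). The lowest autosome was chromosome 2 with 20.2 (19.7 to 20.7). Spans are the end of the last region on each chromosome and include stretches without any region, the longest of which covered 65.2 Mb of chromosome 4.

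The regions that were found on X had a higher fold and less input than autosomal ones. Their median fold was 13.1, against 8.14 ± 0.35 on autosomes, but 18.6% of X regions had no input tag, against 7.94% ± 0.61, and the folds of such regions rest on the 0.5 written for 0. The pooled ChIP to input ratio, which uses 0, was 13.6 on X and 9.80 ± 0.51 on autosomes, 1.39 times as high on X against 1.61 times for the median fold. Their input density was 9.78 tags per kb, against 14.5 ± 0.77. The median fold and the input density lay outside the range of the autosomes, 7.77 to 9.24 for the fold and 12.5 to 16.1 for input. ChIP density on X, 151.6 tags per kb, lay inside the autosomal range of 148.8 to 184.4. The caller's minimum of 14 tags per window is the same on all chromosomes, so lower input by itself raises the fold of listed regions. The higher fold on X is therefore not by itself a measure of more mark. The widest X region ran from 140918668 to 140932195 at a fold of 20.75 (17.0 to 25.6), and the next from 62960675 to 62971243 at 27.6 (21.5 to 36.1). Of the merged domains of 20 kb or more, 5 lay on X, the widest of them 40.6 kb.

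**Figure D3:**
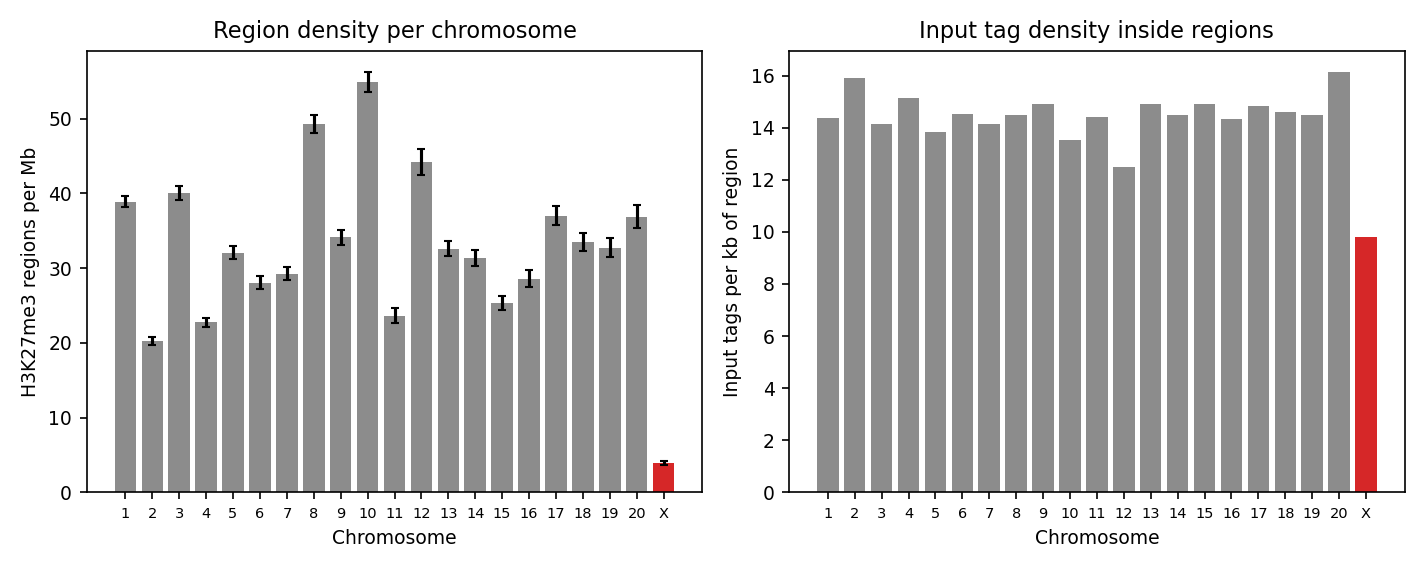
H3K27me3 regions per Mb of span (left, bars with 95% counting intervals) and input tags per kb inside these regions (right) for each chromosome, with X in red. X stands at 3.93 regions per Mb and 9.78 input tags per kb, below all 20 autosomes in both plots.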

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

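The 45 regions on 36 unplaced or random scaffolds lie outside the chromosome comparisons and carried signal above input. They covered 14.9 kb, with a median fold of 11.2, a range from 4.57 to 140.5 and a pooled ChIP to input ratio of 14.4. No input tag lay under 6 of the 45, and the folds of these rest on the 0.5 written for 0. The caller kept only regions with a fold of at least 4, so a fold above input is a condition of being listed.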

How the results depend on the processing

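Among the alternatives planned before the data were examined, the share of regions of 2 kb or wider went from 2.91% to 4.50% when only regions at or above the median fold were kept. It was 3.16% without regions that have no input tag, an alternative chosen after seeing the data. The number of domains of 20 kb or wider went from 533 to 179 with merging at 1 kb, to 2220 with merging at 10 kb, and, added after seeing the data, to 194 among regions at or above the median fold, where fewer regions were left to merge. X stayed lowest of 21 chromosomes under the 6 alternatives tried, with a covered share of 0.149 to 0.216 times the autosome mean, or 0.116 times for regions per Mb. The ratios of wide to narrow ChIP density (2.02 to 2.28) and of narrow regions near wide ones (2.90 to 4.41) stayed above 1 under the 5 alternatives tried for each. The median distance between broad domains, 400.4 kb, became 2472 kb with merging at 1 kb and 145.7 kb at 10 kb, both added after seeing the data, and stayed below the median of the draws. Leaving out each replicate was not run, nor were the settings for promoters, gene bodies, transcription start sites and CpG content. No paired analysis was possible because the 2 libraries form 1 group and the list holds no value per library.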

Other observations

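Long stretches without any region were found on several chromosomes. The longest ran from 67951427 to 133153603 on chromosome 4, over 65.2 Mb, and the next from 20236254 to 40684407 on chromosome 2, over 20.4 Mb. Of 13 stretches of 5 Mb or more, 6 lay on X. Another 30 regions had at least 20 input tags at 50 or more per kb, against a median of 13.3 per kb over all regions, and 23 of them lay within 1 Mb of another such region. The highest input density, 767.9 tags per kb, was on chromosome 14 from 46821546 to 46821770. On chromosome 19 a region from 67047832 to 67049005 held 619 input tags over 1173 bp at a fold of 19.06. The median fold of the 30 was 5.89, against 8.77 in the 4240 other regions with 20 or more input tags. Input is the denominator of the fold, so choosing regions for high input density by itself lowers their fold.

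The tests of the 3 patterns below were added after the data were examined, the test on X regions of 2 kb or wider after its values had been seen at all 3 widths given, the upper bound on X after the lower one had been seen, and the 1 Mb bin test and the merging at 1 and 10 kb after the patterns they bear on had been measured. The first pattern is the low number of regions on X. Stretches without any mapped tags that empty whole 1 Mb bins of X are argued against as the whole cause. Of 155 X bins, 64 were empty, but the median occupied 1 Mb bin of X held 3 regions, against 15 to 40 on the autosomes. The list holds called regions and no coverage by mapped tags, so shorter stretches stay open. One X copy per cell and a fixed tag minimum cannot be told apart from less mark per copy. Autosomal regions with a mean of at least 28 tags per 150 bp, which would still reach the minimum of 14 with their tags divided by 2, numbered 1.60 ± 0.48 per Mb, below the 3.93 on X. This is a lower bound, since a region with a lower mean may hold a window that dense. The upper bound, regions with at least 28 tags in all, was 6.75 to 20.7 per Mb on the autosomes, above X. It is not strict, since a region could break into more than 1. Among regions of 2 kb or wider, those that met the same tag condition numbered 0.365 ± 0.133 per Mb on the autosomes. All such regions on X numbered 0.208 (95% counting interval 0.142 to 0.293). At 5 kb the values were 0.192 ± 0.066 against 0.0714 (0.0356 to 0.128), and at 10 kb 0.0753 ± 0.0338 against 0.0130 (0.00157 to 0.0469). Fewer tags could break a wide region up, so these are not lower bounds on the regions that would stay this wide. At all 3 widths the autosomal mean lay above the upper end of the X interval, while the explanation puts it at or below that end. At none did it exceed that end by 1 SD over autosomes, the bound for arguing against the explanation, with 32, 11 and 2 regions on X. Neither condition was met, so the explanation stays open there too. Without the tag condition X held 0.208 regions of 2 kb or wider per Mb against 0.978 ± 0.348 on autosomes, and 3.24 domains of 20 kb or wider per 100 Mb against 6.42 to 35.5. No biological explanation was tested.

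The second pattern is that narrow regions lie beside wide ones, 4.30 ± 0.87 times as often as the share of span there, or 4.12 times when gaps of 5 Mb or longer are left out of the span. Uneven density of narrow regions between 1 Mb bins makes up part of this: placed evenly within their own bins, 4.51% ± 1.35 of narrow regions would lie this near, against the 8.41% observed. It is argued against as the whole cause, since the ratio of observed to so expected was 1.89 ± 0.21 and above 1 on 20 of 20 autosomes. Narrow regions may in part be fragments of broader domains of low density that the fixed tag minimum breaks up, and unevenness below 1 Mb stays open too, both untested. Whether narrow regions far from wide ones stand above counting noise was not tested, and no biological explanation was tested.

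The third pattern is that autosomal domains of 20 kb or wider lie near one another. Their median distance to the nearest other was 400.4 kb, against 1689 kb in 10000 even random placements (one-sided permutation p = 0.0001, the smallest they can give). An uneven spread of all domains along chromosomes, each counted once, is argued against as the whole cause at a merging distance of 3 kb. Draws of as many domains from all domains of the same chromosome gave a median of 1292 kb and never less than 919.6 kb. Dense stretches of regions merge into few wide domains. The draws therefore cannot test uneven density of the regions themselves, which stays open. With merging at 10 kb the distance, 145.7 kb, again lay below every draw (lowest 257.7 kb). With merging at 1 kb the distance was 2472 kb, shorter than the median draw of 4312 kb (one-sided permutation p = 0.0005). It was not below the lowest draw, 2156 kb, so at 1 kb an uneven spread of all domains stays open. A single larger domain cut by the merging distance stays open as a large part of it: after joining broad domains 100 kb or less apart, 411 were left with a median distance of 1148 kb, shorter than the 1726 kb of the draws (one-sided permutation p = 0.0003) but not shorter than every draw, the bound set in advance. No biological explanation was tested.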
